A study of Sus scrofa with 23 samples.

How the data were processed

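Coronary artery segments of 3 mm from hypercholesterolemic Yorkshire swine, with or without diabetes, had been graded by histopathology and extracted with Trizol, and poly-A selected RNA had been primed at random for sequencing, per the labels' protocols. The series holds 23 libraries. Groups follow the titles: mild, moderate and severe without diabetes (4, 4 and 5 libraries) and moderate and severe with diabetes (6 and 4). The characteristics of severe non-diabetic replicate 5 conflict with its title and were not followed.

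The files used here are 6 tables, 1 per comparison, and no column holds a value of a single library. The authors used the genome build Sscrofa11.1 and the test program DESeq2, per the submitters' processing notes, which give no version. The aligner, the counter and the annotation are not given in the sources used here. The authors deposited for each gene the mean normalized count of each group, a signal that is never negative and is named a normalized mean per the file headers. Its low values fall on as many steps as the group has libraries, as counts divided by 1 size factor per library would. The authors deposited a log2 fold change and its standard error from DESeq2, with the first-named group over the second. The test score that 3 of the authors' deposited tables hold is the fold change divided by its standard error with the sign turned. Directions here follow the fold change and the group means. The p-value and adjusted p-value were deposited by the authors as DESeq2 gave them, and an adjusted p left blank by its filter on low means stays blank here. A p computed here from the deposited fold change and standard error, with a two-sided Wald test, differed from the deposited p by at most 4.39e-15.

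Each table has 35252 lines. In each, 24 held a date in place of a gene name and were left out, which leaves 35228 names. Of these, 5042 had no fold change, 35 had a fold change and no p, and 30151 had a p. Names numbered as copies of 1 gene name made up 943. Names matched the reference gene table of Sscrofa11.1 for 20347 (57.8%), and 7046 of the 19908 names that begin with LOC matched. Coordinates are 1-based, from that table.

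The design fixed before the data were examined foresaw 3 cases, and the last applied: no values per library, so the authors' deposited DESeq2 results were taken as they are, at an adjusted p under 0.05, and no new test per gene was made for the 6 comparisons. That design expected fits of 2 groups each. The standard errors show instead that the authors fitted all 5 groups together, with a spread shared between them. From the standard errors of the 6 comparisons the variance of each group was solved, which gave the implied group sizes of 4, 3.999, 4.999, 6.002 and 4.003. The difference of both diabetes contrasts, severe minus moderate, was tested for each gene with a two-sided Wald test from these fold changes and standard errors, for 17490 genes with a mean of at least 10 over the groups, with Benjamini-Hochberg adjustment.

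Gene lists, 48 with 791 genes, were fixed before the data were examined. Of these genes, 636 matched by the same name, 32 by gene identifier, 16 by synonym, 2 by an older name and 24 by the numbered copy with the highest mean, and 81 were not matched. Each list with at least 5 measured members was tested with limma's cameraPR, two-sided, on the Wald statistics of genes with a mean of at least 10, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. A correlation estimated from the data needs values per library, so preset correlations of 0.05 and 0.1 stood in for it. A count adjusted over the list alone applies the Benjamini-Hochberg adjustment to the members' deposited p.

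Genes are named by a rule fixed before the data were examined. The rule takes the 5 largest rises and the 5 largest falls among genes past the threshold that have a symbol and a mean of at least 20 over both groups. From each list discussed it takes the 2 to 4 members past the threshold with the smallest adjusted p, or at most 2 of smallest p where none passed. It takes the 5 genes of smallest adjusted p for the difference of the diabetes contrasts, and the genes of smallest p where fewer than 10 pass. A list is discussed where its test passes, where at least 3 members pass, or where it is 1 of 11 lists set in advance. Not every gene or list the rule gives is printed. Of 47 lists tested, 24 passed for moderate and 26 for severe against mild segments. For diabetes, 23 passed in moderate and 11 in severe segments. Other names are said to have been chosen after their values were seen.

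Depth was read from the low means. Where a gene had 1 read in 1 library of a group, its mean is a fixed step, and the steps shared by at least 150 genes gave 4, 4, 5, 6 and 4 libraries. They also gave size factors of 0.588 to 1.28 and approximate totals of 6.72 M to 15.0 M reads. A mean of 3 counts over a group would be 0.757, 0.757, 0.594, 0.474 and 0.705 in the order of groups given above, and such floors cover counting error only. The median standard error of a log2 fold change was 0.19 to 0.21 over 12194 genes with a mean of at least 50 in every group.

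The test of the difference, the list test and the counting of steps were tested on simulated data, and the overlaps, the counts over a list alone and the tests of explanations were not. For the difference of the diabetes contrasts, over 17490 genes of which 200 were changed, 27% of changes of 1 (log2) and 81% of changes of 2 (log2) were recovered, and 8 unchanged genes were called. Normal errors were drawn there with the same variances that the test then used. The error rate is therefore not shown for variances that are off, outlying libraries or segments that share an animal. For the list test of moderate against mild segments, over 17490 genes, 5 of 5 lists shifted by 0.5 (log2) were recovered and 0 of 40 other lists passed. The error of each gene was drawn independently there. That simulation therefore does not show how often lists pass when their members vary together. The step counting found 4 of 4 libraries of the mild and 6 of 6 of the moderate diabetic group. Overlaps of comparisons were set against 100 simulated draws with no effect. Alternatives changed the threshold, the filter, the centring and the list test settings. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.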

Results

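RNA was measured in 3-mm segments of coronary arteries of Yorkshire swine, a farm breed of pig, whose cholesterol had been raised and some of which were also diabetic. Serial segments had been graded by histopathology as mild, moderate or severe atherosclerosis. The 23 libraries of poly-A selected RNA fell into 5 groups by their titles. Animals without diabetes gave 4 mild, 4 moderate and 5 severe segments, and diabetic animals gave 6 moderate and 4 severe segments. For 1 library the labels conflict: the title and source name of severe non-diabetic replicate 5 place it there, while its characteristics call it moderate and diabetic. The standard errors of the deposited tables imply group sizes of 4.999 for severe without diabetes and 6.002 for moderate with diabetes, so the authors counted it by its title.

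The deposited tables hold group means and test results for 6 comparisons, and no value per library was used here, so the number of samples that show a direction cannot be given. Steps of single reads in the low means gave approximate library totals of 8.32 M to 13.1 M reads for mild, 6.72 M to 14.3 M for moderate and 8.11 M to 12.6 M for severe segments without diabetes. They gave 10.3 M to 13.3 M for moderate and 11.2 M to 15.0 M for severe segments with diabetes. Over 12194 genes with a mean of at least 50 in every group, the modelled variation between libraries of 1 group had a median of 19.6% of the mean. Unless computed here, each mean, log2 fold change, standard error (given after ±) and p below comes from the authors' deposited tables, in which DESeq2 had fitted all 5 groups together with a spread shared between them. A gene counts as higher or lower at an adjusted p under 0.05. Labels tie no segment to an animal, so p-values of single genes measure the spread between segments, and they are too small wherever segments of 1 animal share a group. The same animals may also have given segments to several groups, so comparisons that share no library may still share animals. Names ending in _1 or _2 are numbered copies of 1 gene name, between which reads may be split. Lists of genes were fixed before the data were examined. Each was set against all other genes with the cameraPR list test, two-sided, whose preset correlation between genes was 0.01. Its p rests on the spread between genes and on that preset value, not on the spread between segments. It is too small where members of a list vary together more than that, as members of 1 tissue or organelle may. Lists overlap, with 46 matched genes on more than 1, so their counts are not independent. ABCA1, ABCG1, APOE and NPC2 are both foam cell and efflux genes, MSR1 is a foam cell and macrophage gene, and SPP1 and LGALS3 are foam cell and modulated smooth muscle genes. MMP9 is both a neutrophil and a matrix protease gene, IL8 and IL1B are NF-kappa B and chemokine genes, PLN is both a contractile and a heart muscle marker, and ATF3 is both an immediate early and an unfolded protein gene.

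**Figure D1:**
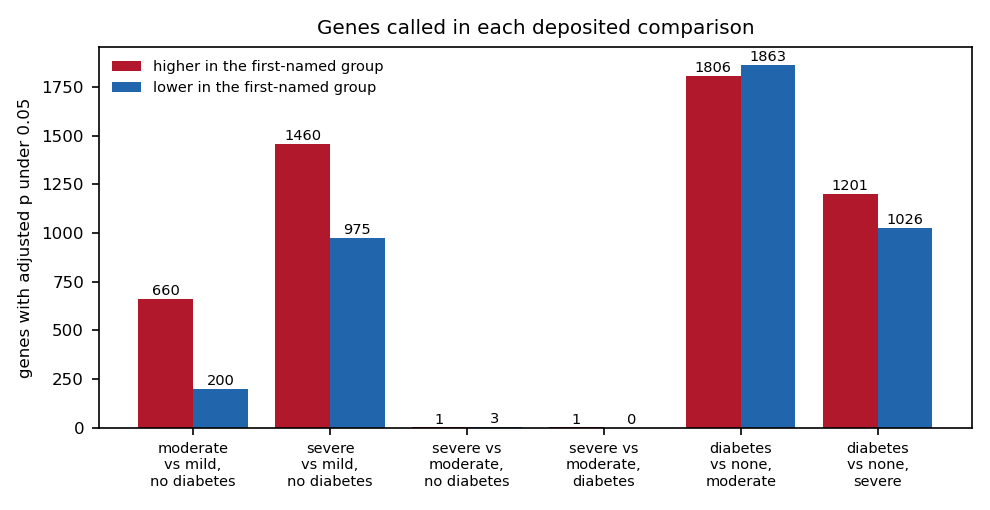
Number of genes higher and lower (adjusted p under 0.05) in each of the 6 deposited comparisons, on a linear axis from 0. Moderate against mild without diabetes gave 660 higher and 200 lower genes, and moderate with against without diabetes gave 1806 higher and 1863 lower, while the 2 comparisons of severe with moderate segments gave 4 and 1 genes in all.

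The first question was which transcripts change as lesions form in animals without diabetes. Moderate segments held more RNA of lipid-handling macrophages, of neutrophil products and of matrix proteases than mild segments. MMP9, a gelatinase that degrades matrix, averaged 67.2 normalized counts in mild and 2351 in moderate segments, 35.1-fold higher in the authors' deposited table (log2 5.13 ± 0.46, adjusted p = 7.86e-25). Transcripts of heart muscle, of lymphatic vessels and of mitochondria were lower as lists. Of 18561 genes with an adjusted p, 660 were higher and 200 lower in the 4 moderate than in the 4 mild segments.

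The authors' deposited table puts the largest other rises, among genes with a symbol and a mean of at least 20 over both groups, at S100A12, a calcium-binding protein of neutrophils (5.27 ± 0.75), CHI3L1, a chitinase-like protein secreted by macrophages (4.79 ± 0.46), arginase ARG1 (4.58 ± 0.80) and TM4SF19 (4.52 ± 0.66), with adjusted p of 1.80e-06 or less. The authors' deposited table puts the largest falls among such genes at the tubulin TUBA8 (-2.61 ± 0.67), lubricin PRG4 (-2.40 ± 0.67), VWC2L (-2.39 ± 0.54), the carbonic anhydrase CA14 (-2.19 ± 0.66) and C3H2orf40 (-2.11 ± 0.69), with adjusted p of 0.0499 or less. C3H2orf40 had an adjusted p of 0.0802 when all genes with a p were adjusted together.

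Of the foam cell and lipid handling list, 12 of the 18 measured members were higher and 0 lower (15 and 0 adjusted over the list alone), with a median log2 fold change of 1.18 (list test, adjusted p = 4.57e-23). The authors' deposited table gives 3.42 ± 0.38 for GPNMB, a glycoprotein of lipid-loaded macrophages, 2.67 ± 0.33 for galectin 3 (LGALS3_1), 2.13 ± 0.28 for the lysosomal protease CTSD and 1.92 ± 0.29 for the scavenger receptor MSR1, with adjusted p of 6.06e-09 or less. Among cholesterol efflux genes and targets of the sterol receptor LXR, 7 of the 15 measured members were higher and 0 lower (8 and 0 adjusted over the list alone; list test, adjusted p = 3.24e-07). They included NPC1, which moves cholesterol out of lysosomes (1.08 ± 0.17, adjusted p = 2.99e-08), the exporter ABCG1 (1.14 ± 0.22, adjusted p = 2.01e-05) and apolipoprotein APOE (1.52 ± 0.35, adjusted p = 0.00101) in the authors' deposited table. Of macrophage markers, 7 of the 17 measured members were higher and 0 lower (7 and 1 adjusted over the list alone; list test, adjusted p = 2.81e-05), among them LAPTM5 (1.37 ± 0.27, adjusted p = 3.14e-05) and the complement receptor VSIG4 (1.07 ± 0.25, adjusted p = 0.00151) in the authors' deposited table.

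Among neutrophil genes 5 of the 11 measured members were higher and 0 lower (5 and 0 adjusted over the list alone; list test, adjusted p = 2.77e-12). The authors' deposited table puts the growth factor receptor CSF3R at 1.59 ± 0.33, adjusted p = 0.000135 and S100A8 at 4.29 ± 0.95, adjusted p = 0.000479. Of matrix proteases and their inhibitors 8 of the 18 measured members were higher and 0 lower (9 and 1 adjusted over the list alone; list test, adjusted p = 7.14e-09). The authors' deposited table gives 4.10 ± 0.83 for the macrophage elastase MMP12, 1.93 ± 0.34 for cathepsin CTSS and 1.58 ± 0.42 for cathepsin CTSK, with adjusted p of 0.00729 or less. Dendritic cell markers counted 3 higher and 0 lower of 12 (3 and 0 adjusted over the list alone; list test, adjusted p = 0.00419). Antigen presentation genes counted 3 higher and 0 lower of 19 (3 and 0 adjusted over the list alone; list test, adjusted p = 0.000499). The chemokine receptor XCR1 stood at 1.37 ± 0.25, adjusted p = 6.75e-06 and the costimulatory molecule CD86 at 1.41 ± 0.24, adjusted p = 6.38e-07 in the authors' deposited table. Of glycolysis genes 3 of the 16 measured members were higher and 0 lower (4 and 0 adjusted over the list alone; list test, adjusted p = 0.00275, and adjusted p = 0.0684 with a preset correlation of 0.1). The authors' deposited table puts hexokinase HK2 at 1.74 ± 0.19, adjusted p = 1.01e-16. Of leukocyte adhesion genes 3 of the 15 measured members were higher and 0 lower (6 and 0 adjusted over the list alone; list test, adjusted p = 0.00347, and adjusted p = 0.0701 with a preset correlation of 0.1). The authors' deposited table puts the selectin ligand SELPLG at 2.14 ± 0.28, adjusted p = 9.69e-12 and the integrin ITGB2 at 1.62 ± 0.25, adjusted p = 1.71e-08.

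Heart muscle markers had a median log2 fold change of -2.03, with 0 of 16 higher and 0 lower (0 and 2 adjusted over the list alone; list test, adjusted p = 3.56e-05). Their share of all normalized counts was 1.60% in mild and 0.429% in moderate segments. Several lists of tissues and organelles moved with them, and whether the smaller share of heart muscle carries these falls was not tested. Mitochondrially encoded genes had a median of -0.90, with 0 of 13 lower (13 adjusted over the list alone; list test, adjusted p = 2.28e-07). Oxidative phosphorylation genes of the nucleus had a median of -0.88 with 0 of 10 lower (10 adjusted over the list alone; list test, adjusted p = 6.99e-06). Of fatty acid oxidation genes 0 of the 18 measured members were higher and 2 lower (0 and 8 adjusted over the list alone; list test, adjusted p = 2.52e-06). ECI1 stood at -1.08 ± 0.32, adjusted p = 0.0217 and the acyl-CoA dehydrogenase ACADL at -1.07 ± 0.33, adjusted p = 0.0305 in the authors' deposited table. Contractile smooth muscle genes had a median of -0.20 and 0 members past the threshold, overall or over the list alone (list test, adjusted p = 0.0420, and adjusted p = 0.254 with a preset correlation of 0.1). Desmin DES stood at -0.97 ± 0.35, p = 0.00561, adjusted p = 0.0912, in the authors' deposited table.

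Of lymphatic endothelial markers 0 of the 7 measured members were higher and 2 lower (0 and 5 adjusted over the list alone; list test, adjusted p = 0.000499). The authors' deposited table puts MMRN1 at -1.51 ± 0.48, adjusted p = 0.0364 and podoplanin PDPN at -1.02 ± 0.32, adjusted p = 0.0383. Adjusted over all genes with a p, MMRN1 had 0.0587 and PDPN 0.0617. Among adventitial fibroblast markers 0 of the 13 measured members were higher and 1 lower (0 and 4 adjusted over the list alone; list test, adjusted p = 0.000294). The microfibril protein MFAP5 stood at -1.93 ± 0.55, adjusted p = 0.0144 in the authors' deposited table. Of endothelial markers 0 of the 16 measured members were higher and 2 lower (0 and 4 adjusted over the list alone; list test, adjusted p = 0.0115, and adjusted p = 0.123 with a preset correlation of 0.1). The authors' deposited table puts PECAM1 at -0.69 ± 0.13, adjusted p = 2.15e-05. Of T cell markers 0 of the 18 measured members were higher and 1 lower (0 and 1 adjusted over the list alone; list test, adjusted p = 0.330), the fall being CD8B (-1.71 ± 0.54, adjusted p = 0.0358) in the authors' deposited table, with 0.0578 adjusted over all genes with a p. Among fibrillar collagen genes 1 of the 16 measured members were higher and 0 lower (1 and 0 adjusted over the list alone; list test, adjusted p = 0.466). Periostin POSTN, a matrix protein of injured vessels, stood at 1.76 ± 0.33, adjusted p = 1.00e-05 in the authors' deposited table. Of modulated smooth muscle genes 3 of the 16 measured members were higher and 0 lower (5 and 2 adjusted over the list alone; list test, adjusted p = 0.00190, and adjusted p = 0.0606 with a preset correlation of 0.1), including osteopontin SPP1 (2.90 ± 0.43, adjusted p = 7.95e-09) in the authors' deposited table.

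Severe against mild segments asked the same question at the far end of the grading. The genes with the largest rises in moderate segments were higher here too, S100A12 (log2 3.20 ± 0.74, adjusted p = 0.000388) and ARG1 (log2 2.41 ± 0.77, adjusted p = 0.0215) by less than in moderate segments in the authors' deposited table. Neither S100A12 nor ARG1 was past the threshold where severe and moderate segments were compared directly. MMP9 averaged 3909.8 normalized counts in the 5 severe segments, 58.4-fold above the 4 mild segments in the authors' deposited table (log2 5.87 ± 0.44, adjusted p = 5.12e-37), and GPNMB was 19.2-fold higher (log2 4.26 ± 0.36, adjusted p = 4.87e-29). Of 20294 genes with an adjusted p, 1460 were higher and 975 lower. Across 17493 genes tested in every comparison, 802 were called in both comparisons with mild segments, 627 higher in both and 175 lower in both, where independent lists would share 52.4 and 10.6. Both comparisons use the same mild libraries: their log2 fold changes had a covariance of 0.313, against 0.0587 simulated with no effect, and part of the overlap may come from the shared libraries.

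The authors' deposited table puts the largest other rises, among genes with a symbol and a mean of at least 20 over both groups, at TCN1, a vitamin B12 carrier (5.20 ± 0.52), ATP6V0D2, a proton pump subunit (4.93 ± 0.47), CHI3L1 (4.92 ± 0.43) and TM4SF19 (4.64 ± 0.65), with adjusted p of 1.02e-10 or less. The authors' deposited table puts the largest falls among such genes at MMRN2_2 (-4.24 ± 0.92), matrilin MATN3 (-3.06 ± 0.80), xanthine dehydrogenase XDH (-3.04 ± 0.99), DAPL1 (-3.02 ± 1.10) and nebulin NEB, a protein of striated muscle (-2.95 ± 0.90), with adjusted p of 0.0496 or less. DAPL1 had an adjusted p of 0.0729 when all genes with a p were adjusted together.

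Of foam cell genes 14 of the 18 measured members were higher and 0 lower (15 and 0 adjusted over the list alone; list test, adjusted p = 1.58e-24). Of cholesterol efflux genes 8 of the 15 measured members were higher and 0 lower (9 and 0 adjusted over the list alone; list test, adjusted p = 8.16e-11). The authors' deposited table gives 2.29 ± 0.33 for APOE, 1.66 ± 0.21 for ABCG1 and 1.12 ± 0.17 for the exporter ABCA1, with adjusted p of 2.17e-09 or less. The cholesterol synthesis list moved the other way: 1 of the 18 measured members were higher and 4 lower (1 and 8 adjusted over the list alone; list test, adjusted p = 0.00263, and adjusted p = 0.0778 with a preset correlation of 0.1). Squalene synthase FDFT1 stood at -0.53 ± 0.11, adjusted p = 3.58e-05, and the member that rose was INSIG1, which restrains sterol synthesis (1.50 ± 0.31, adjusted p = 3.87e-05), in the authors' deposited table.

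Macrophage markers counted 10 higher and 1 lower of 17 (13 and 1 adjusted over the list alone; list test, adjusted p = 5.20e-08). Antigen presentation genes counted 5 and 0 of 19 (7 and 0 adjusted over the list alone; list test, adjusted p = 4.29e-06). Toll-like receptor and inflammasome genes counted 4 and 0 of 16 (9 and 0 adjusted over the list alone; list test, adjusted p = 0.000215). The authors' deposited table gives 1.53 ± 0.31 for SLA-DMB, which loads class II molecules, 1.51 ± 0.27 for TLR8, 1.15 ± 0.24 for NLRP3, the sensor of an inflammasome, and 1.91 ± 0.31 for the complement receptor C5AR1, with adjusted p of 6.96e-05 or less. Of T cell markers 3 of the 18 measured members were higher and 1 lower (3 and 1 adjusted over the list alone; list test, adjusted p = 0.324). The authors' deposited table puts CD28 (LOC100515419) at 2.84 ± 0.65, adjusted p = 0.000397 and CD8B at -1.56 ± 0.51, adjusted p = 0.0243. Of matrix proteases and inhibitors 7 of the 18 measured members were higher and 2 lower (10 and 2 adjusted over the list alone; list test, adjusted p = 4.96e-07). Of osteochondrogenic and calcification genes 7 of the 19 measured members were higher and 0 lower (8 and 1 adjusted over the list alone; list test, adjusted p = 0.0138, and adjusted p = 0.103 with a preset correlation of 0.1). The authors' deposited table gives 2.62 ± 0.32 for CTSS, 3.22 ± 0.41 for SPP1 and 1.05 ± 0.33 for RUNX2, a transcription factor of bone, with adjusted p of 0.0166 or less.

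Contractile smooth muscle genes counted 1 higher and 6 lower of 18 (2 and 7 adjusted over the list alone; list test, adjusted p = 0.00295, and adjusted p = 0.0864 with a preset correlation of 0.1). The authors' deposited table gives -1.40 ± 0.33 for DES, -0.87 ± 0.24 for calponin CNN1 and -0.86 ± 0.25 for tropomyosin TPM1, with adjusted p of 0.00776 or less. Heart muscle markers were lower in the same comparison, 2 of 16 past the threshold (4 adjusted over the list alone) with a median of -2.17 (list test, adjusted p = 0.000384) and a share of counts of 0.400% against 1.60% in mild segments. Mitochondrially encoded genes had 7 of 13 lower (13 adjusted over the list alone; list test, adjusted p = 9.22e-06). Fatty acid oxidation genes had 7 of 18 (8 adjusted over the list alone; list test, adjusted p = 0.000132). Cytochrome b (CYTB) stood at -1.18 ± 0.35, adjusted p = 0.0101 and HADHA at -0.95 ± 0.31, adjusted p = 0.0256 in the authors' deposited table. Of adventitial fibroblast markers 0 of the 13 measured members were higher and 6 lower (1 and 9 adjusted over the list alone; list test, adjusted p = 0.00103). Of lymphatic endothelial markers 0 of the 7 measured members were higher and 4 lower (0 and 5 adjusted over the list alone; list test, adjusted p = 0.00616). The authors' deposited table gives -1.64 ± 0.39 for dermatopontin DPT, -2.19 ± 0.52 for MFAP5 and -1.67 ± 0.48 for the hyaluronan receptor LYVE1, with adjusted p of 0.00719 or less.

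**Figure D2:**
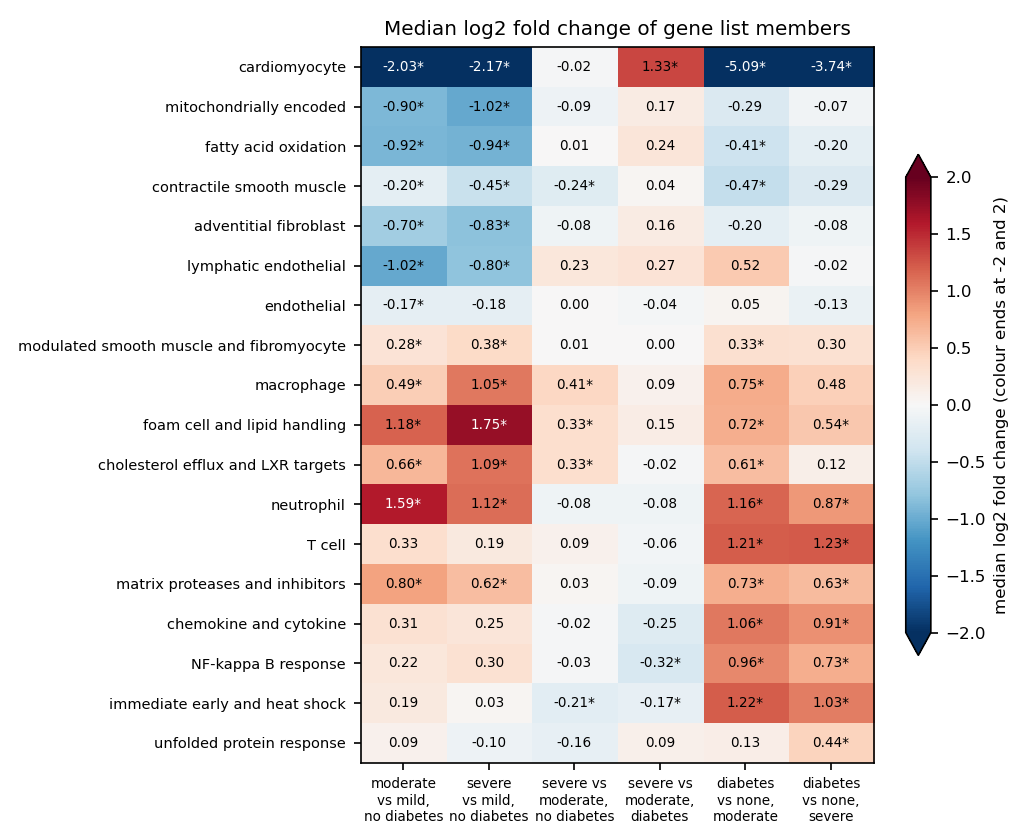
Median log2 fold change of 18 gene lists (vertical axis) in the 6 comparisons (horizontal axis), on a colour scale that ends at -2 and 2, with an asterisk where the list test had an adjusted p under 0.05. The foam cell list was highest in severe against mild segments (1.75), and the heart muscle list was lowest in moderate segments with against without diabetes (-5.09).

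Severe against moderate segments without diabetes asked what changes once a lesion is established. Between the 5 severe and 4 moderate segments, 1 gene was higher and 3 lower of 19716 with an adjusted p by the authors' DESeq2 test, and 850 genes had an unadjusted p under 0.05. With fold changes centred on their median, 3 were higher and 4 lower. The gene that rose was FMN1, a formin that nucleates actin (47.2 and 85.5 normalized counts, log2 0.87 ± 0.19, adjusted p = 0.0337), in the authors' deposited table, with 0.0515 adjusted over all genes with a p, which leaves 0 higher. The authors' deposited table lists the falls as LOC100517243 (692 to 0.662, -10.09 ± 1.78, adjusted p = 0.000267), LOC100512344 (60.8 to 1.38, -5.46 ± 0.98, adjusted p = 0.000267) and LOC100739719 (117 to 3.06, -5.23 ± 1.02, adjusted p = 0.00203), 3 names without a symbol that were given here after their values were seen. The genes of next smallest p were KIAA1211L (1.69 ± 0.40, p = 1.96e-05, adjusted p = 0.0552) and TCN1 (2.08 ± 0.50, p = 3.19e-05, adjusted p = 0.0786), not past the threshold in the authors' deposited table.

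No list below had a member past the threshold over all genes here. Lists of interferon response (median 0.46, list test, adjusted p = 6.83e-07), cholesterol efflux (0.33, adjusted p = 6.83e-07) and foam cells (0.33, adjusted p = 4.44e-06) lay higher in severe segments. The macrophage (0.41, adjusted p = 9.41e-06), antigen presentation (0.28, adjusted p = 0.000212) and complement lists (0.40, adjusted p = 0.000263) did so too. Over the list alone, 3 efflux genes were higher. Lists of cholesterol synthesis (-0.23, adjusted p = 0.000212), nerve and Schwann cells (-0.68, adjusted p = 0.000440), immediate early genes (-0.21, adjusted p = 0.00305, and adjusted p = 0.0863 with a preset correlation of 0.1) and contractile smooth muscle (-0.24, adjusted p = 0.00565, and adjusted p = 0.141 with a preset correlation of 0.1) lay lower. The heart muscle list had a median of -0.02 (list test, adjusted p = 0.709). The authors' deposited table gives 0.46 ± 0.17 for ABCA1 (p = 0.00613), 0.87 ± 0.31 for the haemoglobin receptor CD163 (p = 0.00519), 0.62 ± 0.26 for the antiviral OAS2 (p = 0.0195) and -0.83 ± 0.27 for squalene epoxidase SQLE (p = 0.00173).

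The same question was put in diabetic animals, with 4 severe and 6 moderate segments. Of 30151 genes with an adjusted p, 1 was higher and 0 lower by the authors' DESeq2 test, and 864 had an unadjusted p under 0.05. The gene was LOC102168151 (21.5 to 50.9 normalized counts, log2 1.26 ± 0.25, adjusted p = 0.0170) in the authors' deposited table, named here after its value was seen. Centring on the median gave 1 higher and 2 lower. The next smallest p in the authors' deposited table belonged to the oxidase DUOX2 (-2.66 ± 0.59, p = 5.30e-06, adjusted p = 0.0800) and the integrin ITGA5 (-0.54 ± 0.13, p = 1.80e-05, adjusted p = 0.136), not past the threshold. The heart muscle list lay higher (median 1.33, list test, adjusted p = 0.00385, and adjusted p = 0.201 with a preset correlation of 0.1) and so did the elastic fibre list (0.23, adjusted p = 0.0400, and adjusted p = 0.421 with a preset correlation of 0.1). The NF-kappa B (-0.32, adjusted p = 0.00385, and adjusted p = 0.201 with a preset correlation of 0.1) and immediate early lists (-0.17, adjusted p = 0.00385, and adjusted p = 0.201 with a preset correlation of 0.1) lay lower. FOS, an immediate early transcription factor, stood at -1.33 ± 0.47, p = 0.00514, adjusted p = 1, and the alpha heart myosin MYH6 at 4.27 ± 1.29, p = 0.000947, adjusted p = 1, in the authors' deposited table. MYH6 and MYH7 are near-identical genes between which reads may be split.

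The question of diabetes was put first in moderate segments, 6 with and 4 without it. As lists, genes of inflammatory signalling, chemokines, immediate early factors, T cells and foam cells were higher in diabetic segments, and heart muscle genes lower. The chemokine IL8 averaged 33.1 normalized counts without and 348 with diabetes, 10.6-fold higher (log2 3.40 ± 0.71, adjusted p = 7.35e-05), and MYH6 averaged 6387 and 11.3 (log2 -9.14 ± 1.29, adjusted p = 6.74e-10), in the authors' deposited table. Other genes of the heart's atria, NPPA, MYL7 and MYL4, also had their highest means in moderate segments without diabetes, and the authors' DESeq2 gave them no p, as it does where 1 library lies far from the rest. Whether such a library carries the MYH6 mean is not known. Of 22025 genes with an adjusted p, 1806 were higher and 1863 lower.

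The authors' deposited table puts the largest other rises, among genes with a symbol and a mean of at least 20 over both groups, at IRG1, the itaconate-producing enzyme of activated macrophages (4.16 ± 1.04), IDO1, which breaks down tryptophan (3.06 ± 1.12), FOS (2.93 ± 0.48) and pentraxin PTX3 (2.92 ± 0.80), with adjusted p of 0.0409 or less. IDO1 had an adjusted p of 0.0560 when all genes with a p were adjusted together. The authors' deposited table puts the largest other falls among such genes at COX8H (-6.51 ± 1.61), troponins TNNT2 (-6.45 ± 1.34) and TNNI3 (-6.17 ± 1.31) and myoglobin (MB_1, -6.29 ± 1.41), with adjusted p of 0.00114 or less. All of the heart muscle list fell: 16 of 16 measured members were lower (16 adjusted over the list alone; list test, adjusted p = 3.96e-13), with a share of counts of 0.429% without and 0.0344% with diabetes. When genes at least 2-fold lower in severe than in mild segments without diabetes were left out, a choice made after seeing the data, 3324 genes were called, 1777 of them higher.

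Of NF-kappa B response genes 12 of the 15 measured members were higher and 0 lower (13 and 0 adjusted over the list alone; list test, adjusted p = 6.05e-08). Of chemokines and cytokines 10 of the 23 measured members were higher and 1 lower (14 and 1 adjusted over the list alone; list test, adjusted p = 0.000244). The authors' deposited table gives 1.96 ± 0.39 for BCL3, 1.53 ± 0.32 for the prostaglandin synthase PTGS2, 1.37 ± 0.25 for the adhesion molecule ICAM-1 and 1.68 ± 0.39 for CCL2, which draws monocytes, with adjusted p of 0.000490 or less. Immediate early and heat shock genes moved with them, 9 of 16 higher and 0 lower (9 and 0 adjusted over the list alone; list test, adjusted p = 5.46e-07). The authors' deposited table gives 1.39 ± 0.20 for JUNB, 1.50 ± 0.25 for the phosphatase DUSP1 and 1.26 ± 0.27 for EGR2, with adjusted p of 9.45e-05 or less.

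Of T cell markers 8 of the 18 measured members were higher and 1 lower (11 and 1 adjusted over the list alone; list test, adjusted p = 0.000195). The authors' deposited table gives 2.84 ± 0.41 for the receptor IL7R, 2.87 ± 0.50 for CD28, 2.21 ± 0.60 for the homing receptor CCR7 and -1.84 ± 0.49 for CD8B, the member that fell, with adjusted p of 0.00333 or less. Macrophage markers counted 8 higher and 0 lower of 17 (11 and 0 adjusted over the list alone; list test, adjusted p = 0.000244). Foam cell genes counted 10 and 0 of 18 (12 and 0 adjusted over the list alone; list test, adjusted p = 2.31e-06). Members not past the threshold included TREM2, with a log2 mean of 6.11 without and 5.99 with diabetes. Cholesterol efflux genes counted 7 and 0 of 15 (8 and 0 adjusted over the list alone; list test, adjusted p = 0.000246). The authors' deposited table gives 1.53 ± 0.30 for CD163, 0.95 ± 0.19 for the myeloid factor SPI1, 1.55 ± 0.34 for GPNMB and 0.85 ± 0.15 for NPC1, with adjusted p of 0.000164 or less. Of matrix proteases and inhibitors 8 of the 18 measured members were higher and 0 lower (8 and 0 adjusted over the list alone; list test, adjusted p = 0.000244). The authors' deposited table puts the aggrecanase ADAMTS4 at 1.91 ± 0.31, adjusted p = 1.39e-07. Neutrophil genes counted 4 and 0 of 11 (5 and 0 adjusted over the list alone; list test, adjusted p = 0.00980, and adjusted p = 0.0690 with a preset correlation of 0.1). The authors' deposited table puts lactoferrin LTF at 3.56 ± 0.87, adjusted p = 0.000861.

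Insulin signalling genes went both ways, 3 higher and 1 lower of 19 (3 and 1 adjusted over the list alone; list test, adjusted p = 0.673). The growth factor IGF1 stood at 1.73 ± 0.35, adjusted p = 4.69e-05 in the authors' deposited table. Of oxidative stress genes 7 of the 19 measured members were higher and 2 lower (7 and 2 adjusted over the list alone; list test, adjusted p = 0.0280, and adjusted p = 0.218 with a preset correlation of 0.1). The authors' deposited table puts superoxide dismutase SOD2 at 1.48 ± 0.40, adjusted p = 0.00349. Beside the fall of heart muscle markers, contractile smooth muscle genes counted 0 higher and 4 lower of 18 (0 and 5 adjusted over the list alone; list test, adjusted p = 0.0140, and adjusted p = 0.180 with a preset correlation of 0.1). The authors' deposited table puts smooth muscle myosin MYH11 at -0.72 ± 0.23, adjusted p = 0.0179. Also beside it, fatty acid oxidation genes counted 1 and 3 of 18 (1 and 3 adjusted over the list alone; list test, adjusted p = 0.0383, and adjusted p = 0.238 with a preset correlation of 0.1). Nerve and Schwann cell markers counted 1 and 3 of 11 (1 and 4 adjusted over the list alone; list test, adjusted p = 0.00471, and adjusted p = 0.0690 with a preset correlation of 0.1). The kinase PDK4 stood at -1.94 ± 0.62, adjusted p = 0.0169 and S100B (LOC100623510) at -1.54 ± 0.27, adjusted p = 1.16e-06 in the authors' deposited table. Elastic fibre and basement membrane genes counted 0 and 4 of 18 (0 and 5 adjusted over the list alone; list test, adjusted p = 0.0140, and adjusted p = 0.180 with a preset correlation of 0.1). The authors' deposited table puts elastin ELN at -0.93 ± 0.34, adjusted p = 0.0373, with 0.0510 adjusted over all genes with a p. Endothelial markers had 0 of 16 past the threshold, overall or over the list alone (list test, adjusted p = 0.971).

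Diabetes was then compared in severe segments, 4 with and 5 without it. Chemokines, neutrophil products, T cell markers and immediate early genes were higher with diabetes, and heart muscle markers lower. IL8 was 26.4-fold higher (10.5 and 279 normalized counts, log2 4.72 ± 0.75, adjusted p = 2.16e-07) and S100A12 10.4-fold (log2 3.37 ± 0.60, adjusted p = 5.71e-06) in the authors' deposited table. Of 20869 genes with an adjusted p, 1201 were higher and 1026 lower. The median log2 fold change lay 0.08 above 0, and centring on it gave 720 higher and 1310 lower. Without genes at least 2-fold lower in moderate than in mild segments, again chosen after seeing the data, 2082 genes were called, 1188 of them higher.

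The authors' deposited table puts the largest other rises, among genes with a symbol and a mean of at least 20 over both groups, at SQRDL, a sulfide-oxidising enzyme (6.17 ± 1.74), IRG1 (3.65 ± 1.07), ARG1 (3.47 ± 0.71) and MMRN2_2 (3.44 ± 0.92), with adjusted p of 0.0129 or less. The authors' deposited table puts the largest falls among such genes at the myosin light chains MYL1 (-6.28 ± 2.25) and MLC2V (-4.27 ± 1.42), COX8H (-4.51 ± 1.57), TNNT2 (-4.29 ± 1.39) and myoglobin (MB_2, -4.28 ± 1.46), with adjusted p of 0.0499 or less. Adjusted over all genes with a p, COX8H had 0.0603, MB_2 0.0534 and MYL1 0.0715. Of the heart muscle list 12 of 16 were lower (16 adjusted over the list alone; list test, adjusted p = 5.03e-09), with a share of counts of 0.400% without and 0.0483% with diabetes. Beside it, MYH11 stood at -0.81 ± 0.24, adjusted p = 0.0160 in the authors' deposited table, the 1 contractile smooth muscle gene of 18 past the threshold (1 adjusted over the list alone; list test, adjusted p = 0.129).

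Of immediate early and heat shock genes 10 of the 16 measured members were higher and 0 lower (12 and 0 adjusted over the list alone; list test, adjusted p = 5.38e-08). With them rose 6 of 15 NF-kappa B genes (10 adjusted over the list alone; list test, adjusted p = 1.94e-05). So did 6 of 23 chemokines and cytokines (10 adjusted over the list alone; list test, adjusted p = 0.000198). The authors' deposited table gives 2.42 ± 0.50 for FOS, 1.75 ± 0.40 for EGR3, 2.63 ± 0.41 for CCL2 and 1.27 ± 0.33 for PTGS2, with adjusted p of 0.00425 or less. Of T cell markers 7 of the 18 measured members were higher and 1 lower (10 and 1 adjusted over the list alone; list test, adjusted p = 0.000211). The authors' deposited table puts the costimulator ICOS at 3.13 ± 0.72, adjusted p = 0.000920. Neutrophil genes counted 4 and 0 of 11 (5 and 0 adjusted over the list alone; list test, adjusted p = 0.00132). Foam cell genes counted 7 and 0 of 18 (8 and 0 adjusted over the list alone; list test, adjusted p = 0.000327). The authors' deposited table puts the lipid carrier FABP5 at 1.64 ± 0.33, adjusted p = 9.35e-05. Macrophage markers counted 3 and 0 of 17 (4 and 0 adjusted over the list alone; list test, adjusted p = 0.0734). Of unfolded protein response genes 3 of the 16 measured members were higher and 0 lower (5 and 0 adjusted over the list alone; list test, adjusted p = 0.00112, and adjusted p = 0.0625 with a preset correlation of 0.1). The authors' deposited table puts ATF3 (LOC100738612) at 1.39 ± 0.44, adjusted p = 0.0237. Another of these 3, EIF2AK3, had an adjusted p of 0.0577 over all genes with a p, and of 0.149 with median centring. For SPI1, 1 of the 3 macrophage markers, these values were 0.0641 and 0.0999. Of matrix proteases and inhibitors 5 of the 18 measured members were higher and 0 lower (6 and 0 adjusted over the list alone; list test, adjusted p = 0.00184, and adjusted p = 0.0718 with a preset correlation of 0.1). The authors' deposited table puts ADAMTS4 at 2.26 ± 0.32, adjusted p = 3.67e-09. Of insulin signalling genes 3 of the 19 measured members were higher and 1 lower (3 and 1 adjusted over the list alone; list test, adjusted p = 0.860). The authors' deposited table puts IGF1 at 1.38 ± 0.37, adjusted p = 0.00505 and IGF2 at -1.66 ± 0.48, adjusted p = 0.0103.

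**Figure D3:**
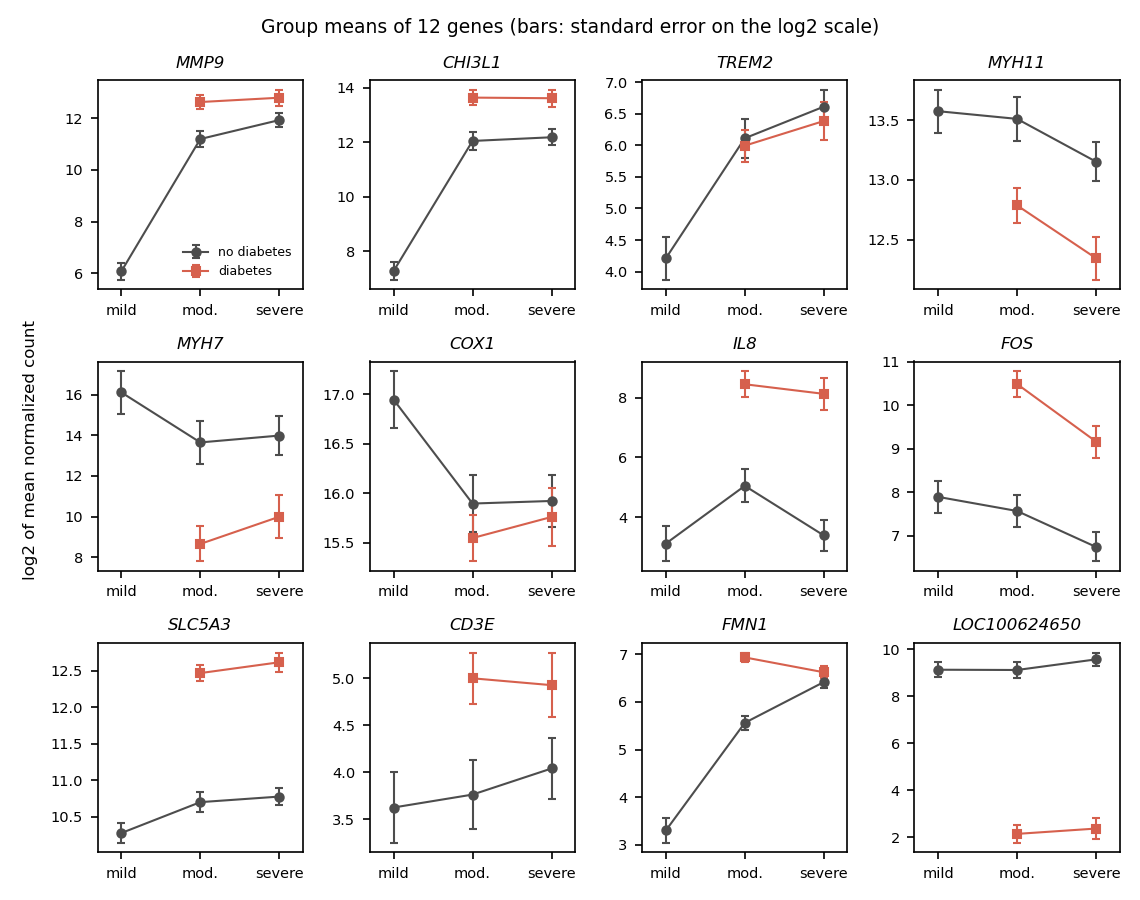
Log2 of the mean normalized count of 12 genes in the 5 groups, with standard errors as bars; panels were chosen after the values were seen. Each panel has its own vertical axis: MMP9 rises from 67.2 in mild to 2351 in moderate segments without diabetes, and the myo-inositol transporter SLC5A3 stands at 1661 without and 5669 with diabetes in moderate segments.

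The design also asks whether diabetes acts differently in severe and in moderate segments. The difference of both diabetes contrasts was tested gene by gene with a two-sided Wald test computed here from the deposited fold changes and standard errors. Of 17490 genes, 2 passed: LOC100512344 (difference 6.06 ± 1.26, adjusted p = 0.0238) and FMN1 (-1.19 ± 0.25, adjusted p = 0.0282), and 705 had an unadjusted p under 0.05. KIAA1211L (-2.40, adjusted p = 0.0572), LOC100517243 (9.98, adjusted p = 0.0865) and CSF2RB (-0.93, adjusted p = 0.0865) had the next smallest p. In list tests of the difference 11 of 47 lists passed, and 3 did at a preset correlation of 0.05 and 0 at 0.1. The diabetes contrast was lower in severe than in moderate segments for 5 of them: interferon (median difference -0.42, adjusted p = 0.000938), antigen presentation (-0.28, adjusted p = 0.00108), cholesterol efflux (-0.32, adjusted p = 0.00149), macrophage (-0.23, adjusted p = 0.0156) and leukocyte adhesion (-0.36, adjusted p = 0.0466). The first 3 of these are the lists that passed at 0.05. It was higher for 6: heart muscle (1.11, adjusted p = 0.0156), cholesterol synthesis (0.28, adjusted p = 0.0156), elastic fibre (0.28, adjusted p = 0.0156), ribosomal protein (0.26, adjusted p = 0.0248), Notch and Wnt (0.19, adjusted p = 0.0258) and unfolded protein response (0.25, adjusted p = 0.0478). For heart muscle, which was lower with diabetes at both grades, higher means a smaller fall. The difference equals the severe against moderate comparison with diabetes minus the same comparison without it. In the comparison without diabetes the interferon, antigen presentation, efflux and macrophage lists lay higher, the cholesterol synthesis list lay lower, and FMN1 and LOC100512344 were called. In the comparison with diabetes the heart muscle and elastic fibre lists lay higher. These results are therefore not separate from those comparisons.

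Across 17493 genes, log2 fold changes with diabetes in moderate and in severe segments, which share no library but may share animals, had a Pearson correlation of 0.786 and a Spearman correlation of 0.712, where genes are not independent replicates. Of 1405 genes called in both, 730 were higher in both, 674 lower in both and 1 opposite, where independent lists would share 115.0 higher and 91.7 lower. Moderate segments with against without diabetes and severe against mild segments without diabetes, again with no shared library, had a Pearson and a Spearman correlation of 0.488, and 1041 genes were called in both, 697 higher, 306 lower and 38 opposite, where independent lists would share 139 and 91.7. The mirror pair, severe segments with against without diabetes and moderate against mild segments without diabetes, also shares no library. Its Pearson correlation was 0.361 and its Spearman correlation 0.265, and 249 genes were called in both, 201 higher, 30 lower and 18 opposite, where independent lists would share 43.4 and 10.6. Both severity grades with diabetes gave the same sign for SLC5A3, which imports myo-inositol, at 1.77 ± 0.17, adjusted p = 8.46e-21 in moderate and 1.84 ± 0.18, adjusted p = 1.02e-20 in severe segments in the authors' deposited tables. NFIL3, a transcription factor of immune cells (1.75 ± 0.21 and 1.73 ± 0.22), the phosphodiesterase PDE4B (1.40 ± 0.19 and 1.37 ± 0.20), complement factor CFB (2.17 ± 0.32 and 2.18 ± 0.31) and AKAP6, an anchoring protein of muscle (-2.22 ± 0.19 and -1.64 ± 0.20), did likewise in the authors' deposited tables. These 5 genes were chosen after their values were seen.

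**Figure D4:**
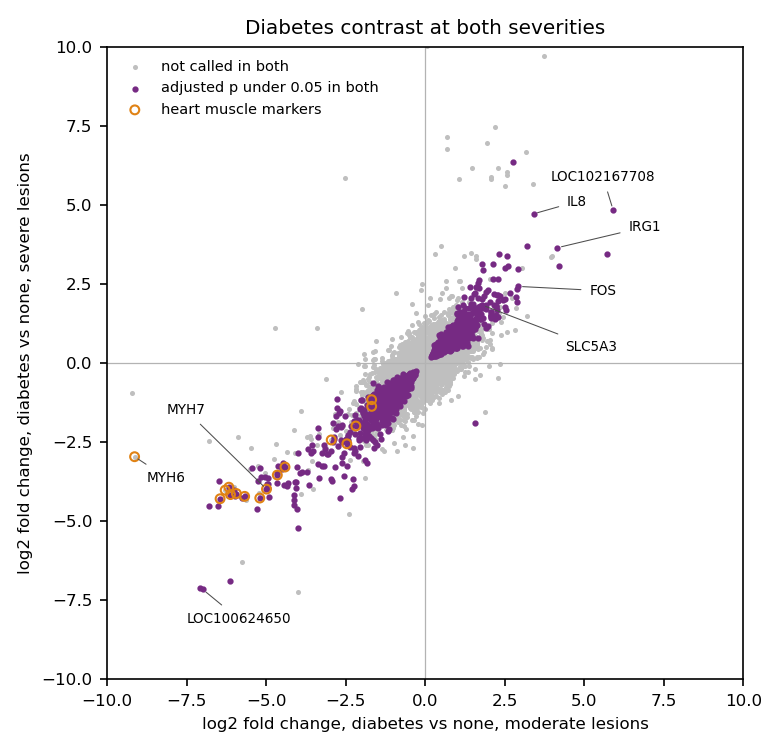
Log2 fold change with diabetes in moderate (horizontal) and severe segments (vertical) for 17509 genes, of which 3 lie outside the axes; darker points are the 1405 genes called in both and orange rings are heart muscle markers. Labelled genes were chosen after their values were seen. Most genes called in both lie in the lower left and upper right of the plot, with heart muscle markers in the lower left.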

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

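The tests of explanations in this part were all chosen after the results were seen.

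The test of the difference between the diabetes contrasts singled out 2 genes. For LOC100512344 the contrast in severe exceeded that in moderate segments by 6.06 (log2, SE 1.26, adjusted p = 0.0238), and its mean was 1.375 normalized counts in severe segments without diabetes against 60.8 to 149.6 in the other groups. For FMN1 the difference was -1.19 (SE 0.25, adjusted p = 0.0282), with means of 9.85, 47.2 and 85.5 from mild to severe without diabetes and of 122 and 98.6 in moderate and severe segments with it. No explanation was tested for either.

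Heart muscle transcripts were lower in diabetic segments, and a candidate explanation is a smaller share of heart muscle left on the diabetic segments. The medians argue against a 2-fold loss of muscle genes of every kind, without a measure of the spread between segments. For 17 contractile smooth muscle markers outside the heart list they were -0.46 (95% interval -0.59 to -0.03) in moderate and -0.27 (-0.46 to 0.16) in severe segments, short of a 2-fold fall. These intervals, and those of the next paragraph, come from resampling the genes of a list. A smaller loss is not excluded: the whole interval in moderate segments lay on the side of a fall, and MYH11 was lower at both severities. A smaller share of heart muscle cannot be told apart from diabetes: 16 of 16 heart muscle markers lay 2-fold or more lower at both severities, but these markers define the pattern and so cannot test it. Whether dissection, the place of a segment along the artery or the disease changed the share stays open, since the labels tie no segment to a position or an animal. Diabetes itself stays among the open explanations, untested.

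Immediate early genes were higher in diabetic segments at both severities. The medians go against more macrophages as the whole cause, but without the spread between segments they cannot exclude it. In severe against mild segments without diabetes the macrophage markers had a median of 1.05, above the 0.75 and 0.48 of the diabetes contrasts in moderate and severe segments. The immediate early list had a median of 0.03 there (95% interval -0.34 to 0.23), below its 1.22 (0.26 to 1.32) and 1.03 (0.63 to 1.39) with diabetes. More T cells cannot be told apart from diabetes, because their markers had a median of 0.19 in severe against mild segments and of 1.21 and 1.23 with diabetes. Tissue handling that differed between the animals cannot be told apart from diabetes, because no batch label crosses the groups. The 12 early response genes had a median of 1.27 in moderate and 1.16 in severe segments and the 4 heat shock genes 0.10 and 0.40, which either account allows. Diabetes may also raise these genes.

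Of 76 genes that differed at least 8-fold with diabetes at both severities, 11 were higher and 65 lower. A smaller share of heart muscle is argued against for 5 of the 55 falling genes with a mean of at least 10 in each group without diabetes, whose change from mild segments excluded a 2-fold fall: LOC100624650, LOC100736635, LOC100736805, ATHL1 and TSPAN7. The other falling genes stay open to it, and 45 fell 2-fold or more from mild to both other grades. A genotype that differs between diabetic and other animals cannot be told apart from diabetes without animal labels: of the 31 genes outside falls like those of heart muscle 18 were located, and 2 pairs lay within 200 kb, against a mean of 0.03 and a highest of 1 in 100 random draws. Of all 76 genes 49 were located, with 3 pairs, against a mean of 0.48 and a highest of 2. Random genes were drawn only among those with a mean of at least 10 over the groups, a floor not set for the observed genes. LOC100302368 and LOC102166836, with highest group means of 8.094 and 7.751, could not be drawn. The draws are therefore no like measure for the pairs. The pair LOC100302368 and LOC102166836, a variable segment inside it, rose together, as the T cell list did. The others were LOC100736805 with PLCH2 and COX8H with LOC100626247. LOC100624650, a transcribed pseudogene on X at 60626452 to 60627184, had means of 557, 552 and 755 without and 4.41 and 5.16 with diabetes.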

How the results depend on the processing

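The median centring, the filters on mean count, the list test settings and the removal of genes that fall with severity were chosen after seeing the data. Of the summary counts, 57 stayed within 1.5 times of the reported count and 25 moved further. These figures compare totals and not directions. For diabetes in severe segments, median centring called 2030 genes against 2227, which counts as within. There 720 were higher and 1310 lower, against 1201 and 1026, and 1746 genes were called both ways. The alternatives run on named genes could hardly change a direction. Removing the filter keeps each fold change, and centring shifts all genes of a comparison alike, by at most 0.08 (log2). With no filter, 377 called values of genes the rule gives kept the call and 40 lost it, and with median centring 396 kept it and 21 lost it. At an adjusted p under 0.01, genes called were 480 for moderate and 1364 for severe against mild, 0 for severe against moderate with diabetes, and 2017 in moderate and 941 in severe segments for diabetes. At 2-fold or more they were 492, 1238, 1494 and 929 for the same comparisons, leaving out the 0. Severe against moderate without diabetes gave 7 genes with median centring and 7 at a mean of 10 or more, and with diabetes 3 and 2. List tests past the threshold fell at a correlation of 0.1 to 13 for moderate and 14 for severe against mild, 8 and 0 for severe against moderate without and with diabetes, 9 and 7 for diabetes in moderate and severe segments, and 0 for the difference of the diabetes contrasts. At a correlation of 0.05 they were 15 for diabetes in moderate segments and 3 for the difference. Severe against moderate with diabetes gave 8 lists with ranks and 9 with no filter, and diabetes in severe segments 20 with no filter. Stricter thresholds and higher correlations call less by construction, and for the rest the cause was not tested. No paired analysis was possible because the tables give no value per library. For the same reason another test or normalization, pseudocounts, a fit of all libraries, each replicate left out, severe non-diabetic replicate 5 left out or moved, an estimated correlation, fry and other splits of the samples were not run. Means near the floor of 3 counts limit the rarest genes.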

Other observations

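The values in this part were all chosen after they were seen, and no test was run on them here.

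The authors' deposited tables hold 35 genes with a fold change and no p, and 14 of these had their highest mean in severe segments with diabetes. Most of the 14 have no symbol. The J chain gene IGJ averaged 120.4 normalized counts there, against 41.7 to 48.2 in the other groups, and MZB1, a plasma cell protein, averaged 7.66. LOC396781 averaged 704 against 43.8 in moderate segments with diabetes, and the variable segment LOC100736878 averaged 404 against 25.6. The list of B and plasma cell genes, on genes with a p, had a list test adjusted p of 0.820 for diabetes in severe segments. DESeq2 leaves the p blank for genes in which 1 library lies far from the rest, and values per library were not used here, so the number of segments behind these means is not known.

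Of the 35 genes without a p, 18 had their highest mean in moderate segments without diabetes, several of them genes of the heart's atria and of nerve cells. NPPA, the atrial natriuretic peptide, averaged 1757 normalized counts there and 149 in mild segments, and is listed at 0 in moderate segments with diabetes. The atrial light chains MYL7 and MYL4 averaged 830.4 and 1193, against 88.7 and 388 in mild segments. The neurofilament NEFL averaged 173 against 14.1, and the synaptic protein SNAP25 26.5 against 1.18.

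LOC102167708, a long noncoding RNA on chromosome 16 at 6170442 to 6214121, averaged 0.916, 3.23 and 6.56 without and 169.8 and 184 normalized counts with diabetes. The retinoid-binding CRABP1 averaged 46.4 and 36.9 in moderate and severe segments without and 2.65 and 1.75 with diabetes. MMRN2_2 averaged 23.1 in severe segments without diabetes, against 246 in moderate segments without and 249.9 in severe segments with it.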
